A study of Mus musculus with 12 samples.

How the data were processed

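The series holds RNA-seq of 12 libraries of mouse bone-marrow-derived macrophages, labelled WT or CKO and untreated or treated for 24 h with IFN-γ (100 U/mL) or IL-4 (20 ng/mL), 2 libraries per group. The deposited table holds raw counts per gene, as whole numbers that sum to different totals per library, and the authors made them, per the submitters' processing notes, with CASAVA 1.8.2, TopHat2 2.0.13, Picard 1.97 and HTSeq 0.6.1. Per the submitters' processing notes, the builds were GRCh38 and mm10, without the role of each; the identifiers in the deposited file are mouse Ensembl gene identifiers. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands are uncertain. Whether the libraries of a group came from different animals, and what the shared numbers 1 and 2 stand for, is not stated in the labels.

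From the 48440 genes, 22932 had no count in any library, and 16292 were kept by edgeR's filterByExpr over the 6 groups. Symbols came from the deposited file. Positions came from GENCODE M21 on GRCm38, where 40606 identifiers matched with their version and 48058 without it, and positions were printed only for genes whose identifier matched. Library totals ran from 21287725 to 32717379 counts. Shares of counts in a single library have 95% Wilson intervals. Where a group had no count of a gene, its fold is a lower bound computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has a 95% exact counting interval. Intervals and floors cover counting error only.

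The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling and robust dispersions in 1 fit of 6 group means to all 12 libraries, with 6 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05 within each of 9 comparisons: CKO against WT in each treatment, each cytokine against untreated in each genotype, and the 2 genotype by treatment interactions. The SE printed is the absolute log2 fold change over the square root of the F statistic and is approximate. The tests, comparisons, gene lists and the rule for naming genes were fixed before the data were examined. The 26 fixed lists were taken from textbook knowledge of macrophages and of other cells of a marrow culture, and 23 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with p-values adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it, and counts of list members are given adjusted over all genes and adjusted over the list alone. List medians were also computed with genes at the floor set to their bound.

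Genes were named by this rule. In each of the 7 two-group comparisons, among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the 4 libraries, the 8 largest increases and 8 largest decreases were eligible, and in each interaction the 5 most positive and 5 most negative without the overlap condition. From each fixed list with a call, up to 3 members with the smallest adjusted p were added, and Irf8 was named throughout. Genes without a proper symbol were not named, and an item withheld for evaluation is not reported here. Nnt, Wdfy1, Glo1, Rps2 and its copies, Gapdh, Actb, mt-Rnr2, Xist, Ddx3y, Eif2s3y and Kdm5d, and the genes picked from those shared by the 3 genotype comparisons, were chosen after their values were seen.

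Overlaps of calls are set against independent lists (the product of both numbers of calls over the genes tested), and those of comparisons with shared controls also against 20 simulated draws of unchanged groups. The alternatives tried were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter on low counts, a stricter filter at a mean CPM of 5, a fold threshold of 2 beside the adjusted p, only the compared groups in the fit, the library number as a block, that block within genotype, and leaving out 1 library at a time. For a group reduced to 1 library, the lone library is assumed to vary like the other groups. Without untreated CKO library 2 the untreated CKO group is library 1 alone, which stood apart in its RNA shares. Higher numbers of calls in that fit cannot be told apart from the traits of library 1. A fit that leaves untreated CKO library 1 out of the shared spread was added after seeing the data. The edgeR and DESeq2 steps were tested on simulated counts built from the real means, dispersions and library sizes. In the untreated genotype comparison, run on 15924 genes, edgeR recovered 63.9% of 2-fold and 91.8% of 4-fold changes with 7 false calls among 159. In the IFN-γ interaction it recovered 33% and 84.7% with 8 false among 123. DESeq2 made more false calls on the same counts, 18 among 171 and 22 among 145. The counts were drawn with 1 mean per gene, edgeR's own dispersions and changes only in untreated CKO, and no library stood apart. These rates need not hold in the real data, and they do not rank the tools. The permutation and Fisher tests were run in R, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main test. Splits of the libraries into other groups were not tested, since groups of 2 are too small for it, and reads were not analysed here, so there are no counts per exon.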

Results

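RNA was sequenced from mouse bone-marrow-derived macrophages, cells grown from marrow precursors in culture. The labels give the genotype as wild type (WT) or CKO. Cells of each genotype were left untreated, given interferon-gamma (IFN-γ, 100 U/mL), a T cell cytokine that arms macrophages against infection, or given IL-4 (20 ng/mL), a cytokine of allergy and wound repair, for 24 h. The 12 libraries form 6 groups, with n = 2 libraries per group throughout, and the series title names the transcription factor IRF8 and an anti-metastatic program. Totals ran from 21287725 to 32717379 counts per library, and 16292 of 48440 genes had enough counts to be tested. Values are counts scaled to library size (CPM) as mean ± SD and log2 fold changes ± SE, where the SE is approximate. The p-values measure the spread between libraries, which may be technical, because the labels do not say whether the libraries of a group came from different animals. Intervals and floors cover counting error only. Untreated CKO library 1 stood apart: mitochondrial genes took 1.52% of its counts (95% Wilson interval 1.515 to 1.525) against 2.12% to 3.25% in the other 11, and the ribosomal RNA gene mt-Rnr2 took 0.298% (95% Wilson interval 0.2959 to 0.3001) against 0.925% to 1.54%. Its Gapdh level was 323 CPM, the lowest of the 12 libraries. The 7SL RNA genes took 7.6% of its counts (95% Wilson interval 7.59 to 7.61) against 5.25% to 6.32% in the others. Gm42418, which overlaps ribosomal RNA sequence, took 1.28% in that library (95% Wilson interval 1.276 to 1.284), 1.05% in untreated WT library 1 (1.046 to 1.054) and 0.753% in IFN-γ WT library 1 (0.7496 to 0.7564), against 0.0717% to 0.174% in the other 9.

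Irf8, the gene of the factor named in the series title, came first as a check on the labels. Irf8 (ENSMUSG00000041515.9; GRCm38 chromosome 8, 120736358 to 120756694, plus strand) was present in every library and was higher in those labelled CKO. Untreated libraries held 91.1 ± 0.228 CPM of Irf8 in WT and 270 ± 31.7 in CKO (log2 fold change 1.57 ± 0.12, edgeR adjusted p = 1.25e-05). After IFN-γ the levels of Irf8 were 508 ± 7.77 and 1190 ± 21.8 CPM (log2 fold change 1.23 ± 0.11, edgeR adjusted p = 2.81e-05), and after IL-4 they were 68.3 ± 3.69 and 154 ± 20.6 CPM (log2 fold change 1.17 ± 0.11, edgeR adjusted p = 0.00023). A loss of the whole transcript would lower these counts, so Irf8 goes against the label. Counts over a whole gene do not check a deletion of single exons, and every direction below is between libraries labelled CKO and libraries labelled WT. IFN-γ raised Irf8 in both genotypes (log2 fold change 2.48 ± 0.12 in WT, edgeR adjusted p = 2.07e-08, and 2.14 ± 0.12 in CKO, edgeR adjusted p = 5.87e-08). IL-4 lowered Irf8 in CKO (−0.81 ± 0.11, edgeR adjusted p = 0.000388). Its fall in WT (−0.42 ± 0.11, edgeR adjusted p = 0.0336) was not past the test without any one of the 4 libraries compared, untreated WT library 1 or 2 or IL-4 WT library 1 or 2, with log2 fold changes from −0.48 to −0.37. Neither response of Irf8 differed between genotypes past the test (interaction −0.34, edgeR adjusted p = 0.394, for IFN-γ and −0.39, edgeR adjusted p = 0.773, for IL-4).

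Lyz2 separated the genotypes in every library. Lyz2 (ENSMUSG00000069516.7; GRCm38 chromosome 10, 117277331 to 117282321, minus strand) encodes lysozyme, the main bactericidal enzyme of macrophages. It lay between 5840 and 11900 CPM in the WT libraries and between 12.6 and 28 CPM in the CKO libraries. Its log2 fold change was −8.73 ± 0.17 without cytokine, −8.71 ± 0.17 after IFN-γ and −8.85 ± 0.18 after IL-4 (edgeR adjusted p = 9.96e-11, 1.06e-10 and 9.3e-11). The neighbouring paralog Lyz1 fell by 4.21, 3.75 and 4.16 on the log2 scale, and its values are uncertain because reads of these near-identical genes can be assigned to either.

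**Figure D1:**
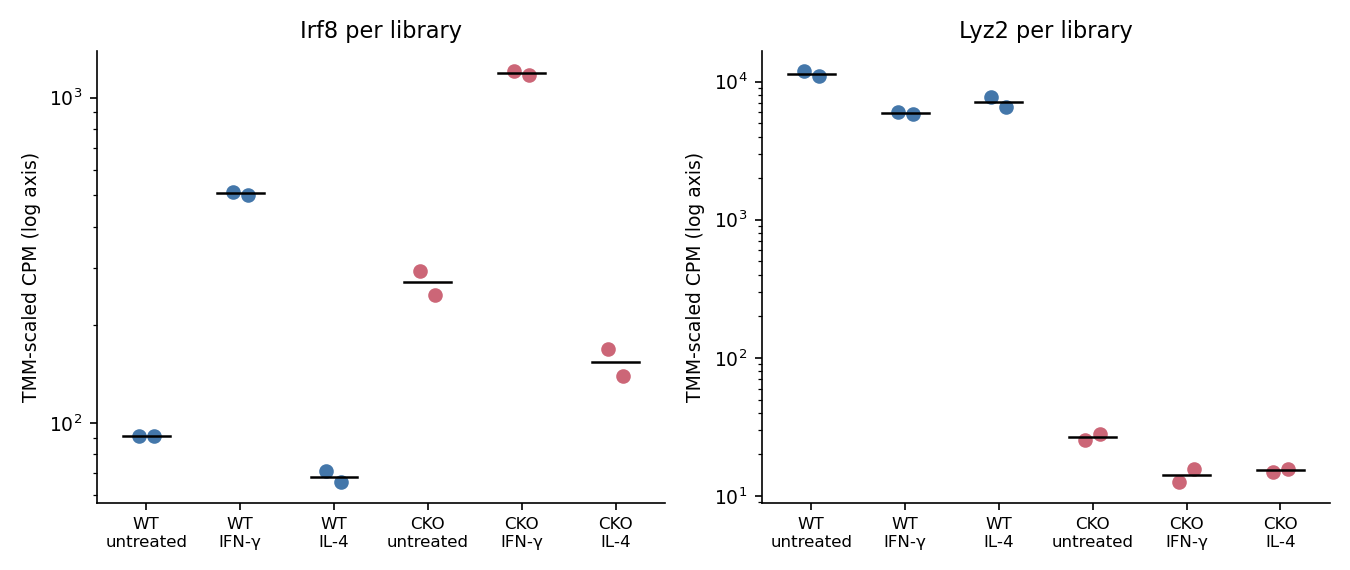
Counts scaled to library size (CPM) of Irf8 and Lyz2 on log axes in each of the 12 libraries, by genotype label and treatment, with points for libraries and bars for group means. Irf8 is higher in the libraries labelled CKO in each treatment, and Lyz2 lies at 5840 CPM or more in every WT library and at 28 CPM or less in every CKO library.

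Without cytokine the comparison of CKO with WT asks what the genotype changes in resting macrophages. Genes of neutrophils and their precursors were higher in CKO: 19 of the 23 tested members rose (20 adjusted over the list alone) and 4 did not pass, with a median log2 fold change of 2.17. S100a8, a calcium-binding protein stored by neutrophils, rose from 10.3 ± 1.27 to 69.9 ± 28.2 CPM (log2 fold change 2.77 ± 0.25, edgeR adjusted p = 9.42e-05), and Lcn2, which withholds iron from bacteria, rose by a log2 fold change of 2.47. Of 15 monocyte markers, 13 rose (15 adjusted over the list alone), among them the chemokine receptor gene Cx3cr1 (2.38 ± 0.448 to 15.4 ± 3 CPM) and Hp, which encodes a hemoglobin-binding plasma protein (log2 fold change 3.23 ± 0.28). Abca9, a lipid transporter gene, rose from 1.28 ± 0.125 to 73.2 ± 22.8 CPM (log2 fold change 5.83 ± 0.26, edgeR adjusted p = 4.27e-07). Id3, an inhibitor of helix-loop-helix transcription factors, rose by 3.29, and the kinase gene Sik1 by 3.62. Cholesterol synthesis genes moved down: 21 of 24 fell (23 adjusted over the list alone), with a median of −0.75, as in Lss (103 ± 11.6 to 45.6 ± 11.6 CPM) and Cyp51 (log2 fold change −0.94 ± 0.11). Glycolysis genes fell in 13 of 20 cases (17 adjusted over the list alone), including Ldha (log2 fold change −0.84 ± 0.12) and the lactate exporter gene Slc16a3 (−0.95 ± 0.12).

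Complement and surface genes of mature macrophages went both ways in the same comparison. The 3 genes of the C1q complex, which tags cells and debris for uptake, fell together: C1qb from 487 ± 21.5 to 38.9 ± 15 CPM (log2 fold change −3.65 ± 0.25, edgeR adjusted p = 1.25e-05), C1qa by a log2 change of −4.22 and C1qc of −2.28. C3, the central complement protein, rose from 10.1 ± 0.221 to 38.7 ± 3.87 CPM (log2 fold change 1.93 ± 0.12, edgeR adjusted p = 2.79e-06). Over the 18 complement genes 2 rose and 6 fell, the same numbers adjusted over the list alone. Cd40, a receptor for T cell help, fell from 5.42 ± 0.103 to 0.64 ± 0.00756 CPM, and Fcgr1, the high-affinity IgG receptor gene, by a log2 change of −1.65. The macrophage identity list split, with 9 of 26 higher and 7 lower (9 and 8 adjusted over the list alone). Its median was −0.02 and its mean −0.40. Genes of matrix remodelling and vessel growth, the group closest to the metastasis named in the title, fell in 14 of 35 cases and rose in 6 (18 and 6 adjusted over the list alone). Mmp12, a macrophage elastase gene, dropped from 1010 ± 268 to 317 ± 48.6 CPM, Lgals3 had a log2 fold change of −0.95, and the collagenase gene Mmp8 rose from 188 ± 11 to 611 ± 88 CPM. Of the interferon-induced GTPases, which attack vacuoles of intracellular microbes, 7 of 20 rose (9 adjusted over the list alone), for example Gbp8 (0.795 ± 0.16 to 9.39 ± 3.09 CPM). Known IRF8-dependent myeloid genes rose in 9 of 36 cases and fell in 3, the same numbers adjusted over the list alone. Of the cell cycle genes 10 of 46 fell and 1 rose (17 and 1 adjusted over the list alone).

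In that untreated comparison edgeR called 2927 genes, 1401 higher and 1526 lower in CKO. The count was 866 without WT library 1, 891 without WT library 2, 914 without CKO library 1 and 5034 without CKO library 2. Camera, a test of a list against all other genes, called the neutrophil list up (adjusted p = 1.32e-26; adjusted p = 0.0552 with an estimated correlation) and the monocyte list up (camera adjusted p = 1.2e-21; adjusted p = 0.00583 with an estimated correlation). It called the cholesterol list down (camera adjusted p = 6.97e-18; adjusted p = 0.167 with an estimated correlation), glycolysis down (camera adjusted p = 2e-08; adjusted p = 0.227 with an estimated correlation) and the cell cycle down (camera adjusted p = 2.41e-08; adjusted p = 0.502 with an estimated correlation). GTPases were up (camera adjusted p = 5.33e-07; adjusted p = 0.309 with an estimated correlation), IRF8-dependent genes up (camera adjusted p = 0.00148; adjusted p = 0.476 with an estimated correlation) and matrix genes down (camera adjusted p = 0.00211; adjusted p = 0.0902 with an estimated correlation). Complement was down (camera adjusted p = 0.0361; adjusted p = 0.373 with an estimated correlation) and macrophage identity down (camera adjusted p = 0.0197; adjusted p = 0.167 with an estimated correlation), and without CKO library 2 neither was past the test (camera adjusted p = 0.169 each). The complement median changed sign, with 0.09, −0.19, −0.09 and 0.06 without WT library 1, WT library 2, CKO library 1 and CKO library 2. List counts changed when 1 library was left out. Such a fit leaves 1 library in a group, so a lower count alone does not show that a list leaned on the library left out. Without CKO library 2 the untreated CKO group is library 1 alone, which stood apart. The 10 lower cell cycle genes became 1 without WT library 1, WT library 2 or CKO library 1 and 43 without CKO library 2, with a list median of −0.54 in all libraries, −0.19 without CKO library 1 and −0.96 without CKO library 2. The 1 higher cell cycle gene was lost without WT library 1, WT library 2 or CKO library 2. The 13 lower glycolysis genes became 7 without WT library 1, WT library 2 or CKO library 1. The 21 lower cholesterol genes became 12 without WT library 2 and 19 without CKO library 1, and the 13 higher monocyte markers became 8 without WT library 2. The 7 higher GTPases became 4 without WT library 1 or 2 and 3 without CKO library 1, and the 9 higher identity genes became 4, 3 and 4 without WT library 1, WT library 2 and CKO library 1, with an identity median of −0.04, 0.22, 0.10 and −0.09 without WT library 1, WT library 2, CKO library 1 and CKO library 2. The 2 higher complement genes became 1 without WT library 1 or 2 and 4 without CKO library 2. The 6 higher matrix genes became 3 without WT library 2. The 9 higher IRF8-dependent genes became 4 without WT library 2 and 15 without CKO library 2, and the 3 lower ones became 1 without WT library 1 or CKO library 1. The 19 higher neutrophil genes became 14 without CKO library 1, with a median of 1.61. Gapdh had a log2 fold change of −0.74 ± 0.19 in this comparison (edgeR adjusted p = 0.0248) and Actb of −0.40 ± 0.13 (edgeR adjusted p = 0.0559). Gapdh was no longer past the test without CKO library 1 (−0.39, edgeR adjusted p = 0.0694), WT library 1 (edgeR adjusted p = 0.0773) or WT library 2 (edgeR adjusted p = 0.115).

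**Figure D2:**
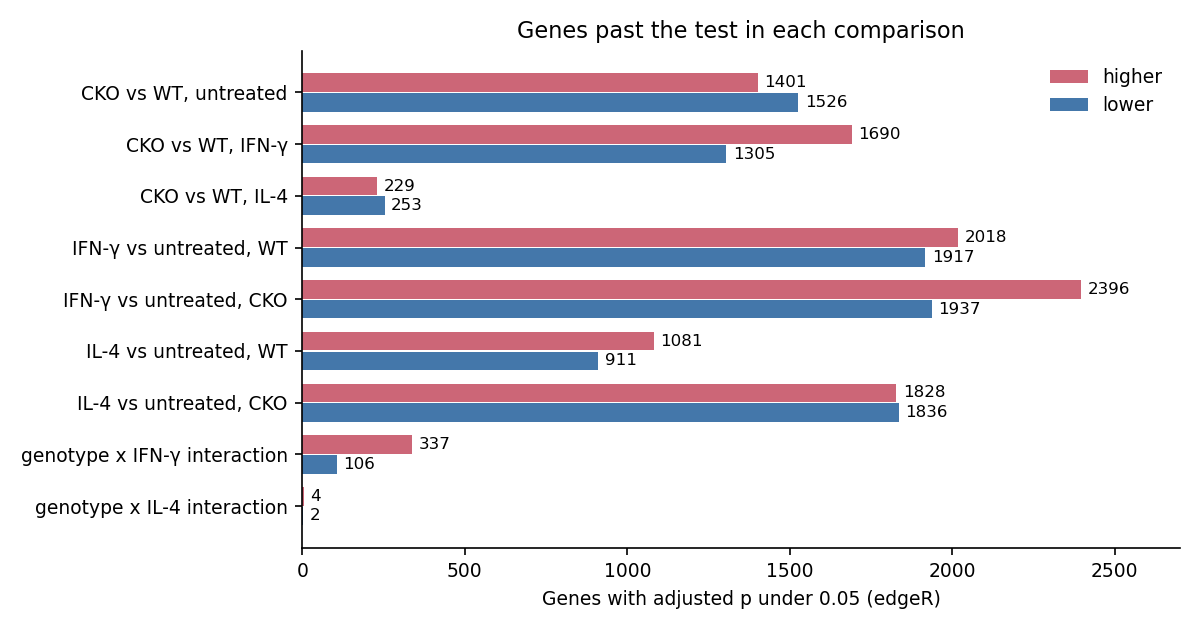
Number of genes past an edgeR adjusted p of 0.05 in each of the 9 comparisons, higher and lower separately, in the fit to all libraries. The untreated genotype comparison had 2927 calls and the IL-4 interaction had 6. The dependence of these numbers on single libraries is not drawn and is given in the text.

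After IFN-γ the genotype comparison asks whether the interferon-activated state differs. Antiviral interferon-stimulated genes were higher in CKO: 32 of 43 rose and 2 fell (35 and 2 adjusted over the list alone), with a median log2 fold change of 0.84. Irf7, the master regulator of type I interferon, rose from 62.4 ± 8.12 to 198 ± 7.45 CPM (log2 fold change 1.67 ± 0.11, edgeR adjusted p = 3.63e-06), and the antiviral gene Oasl2 rose by 1.66. Genes of antigen presentation on MHC class I rose in 16 of 23 cases and fell in 1 (18 and 1 adjusted over the list alone), for example H2-K1 (983 ± 63.8 to 1920 ± 48.8 CPM) and the peptide transporter gene Tap2 (log2 fold change 0.73 ± 0.10). Of the GTPases 11 of 20 rose and 1 fell (13 and 1 adjusted over the list alone), with Igtp at 445 ± 37.5 CPM in WT and 1100 ± 11.6 in CKO. Genes of IFN-γ signalling rose in 13 of 29 cases and fell in 2 (15 and 5 adjusted over the list alone). Complement rose in 9 of 18 cases and fell in 3 (10 and 3 adjusted over the list alone): C3 went from 68.6 ± 7.57 to 729 ± 54 CPM (log2 fold change 3.41 ± 0.12, edgeR adjusted p = 2.39e-08), and C4b had a log2 fold change of 1.84 ± 0.23.

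Neutrophil genes were again higher after IFN-γ in 19 of 23 cases (20 adjusted over the list alone), with a median of 2.31, including Padi4, whose enzyme opens neutrophil chromatin (1.34 ± 0.269 to 9.39 ± 0.45 CPM). Monocyte markers rose in 13 of 15 cases (13 adjusted over the list alone), with Hp at a log2 fold change of 5.05 ± 0.30 and Cx3cr1 at 5.39 ± 0.32. Large single changes included rises of the endothelin receptor gene Ednrb (13.8 ± 1.25 to 206 ± 1.04 CPM), the kinase gene Fgr (log2 fold change 3.68 ± 0.15) and the sterol-sensing receptor gene Nr1h3 (3.22 ± 0.15). Genes that fell included Clec9a, a receptor for dying cells on dendritic cells (48.2 ± 6.35 to 5.99 ± 0.686 CPM), Batf3, a regulator of the same dendritic cells (log2 fold change −2.17 ± 0.29), Ocstamp, which takes part in macrophage fusion (102 ± 5.19 to 11 ± 0.517 CPM), and Ptgs2, the inducible prostaglandin synthase gene (207 ± 93.3 to 21 ± 8.85 CPM). Matrix genes split, 11 of 35 higher and 8 lower (11 and 10 adjusted over the list alone), with Mmp9 at a log2 fold change of 2.66 ± 0.30. Glycolysis fell in 12 of 20 cases (12 adjusted over the list alone) and the cell cycle in 23 of 46 (30 adjusted over the list alone), with Ccnb1 at a log2 fold change of −1.02 ± 0.17. Macrophage identity genes had medians of 0.43, 0.39, 0.29 and 0.48 without WT library 1, WT library 2, CKO library 1 and CKO library 2. The camera calls of this list as down, without cytokine and after IL-4, thus had no lower median beside them after IFN-γ.

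After IFN-γ edgeR called 2995 genes between genotypes, 1690 higher and 1305 lower in CKO. The count was 1890 without WT library 1, 1875 without WT library 2, 1209 without CKO library 1 and 1496 without CKO library 2. Camera called antiviral genes up (adjusted p = 3.14e-26; adjusted p = 0.0857 with an estimated correlation), neutrophil genes up (camera adjusted p = 3.43e-27; adjusted p = 0.0486 with an estimated correlation) and monocyte markers up (camera adjusted p = 7.38e-22; adjusted p = 0.00284 with an estimated correlation). Also up were GTPases (camera adjusted p = 3.9e-08; adjusted p = 0.265 with an estimated correlation), MHC class I (camera adjusted p = 2.1e-07; adjusted p = 0.265 with an estimated correlation), IFN-γ signalling (camera adjusted p = 2.52e-05; adjusted p = 0.259 with an estimated correlation) and complement (camera adjusted p = 4.11e-06; adjusted p = 0.0857 with an estimated correlation). Glycolysis (camera adjusted p = 3.9e-08; adjusted p = 0.259 with an estimated correlation) and the cell cycle (camera adjusted p = 2.87e-12; adjusted p = 0.416 with an estimated correlation) were down. Some list counts changed when 1 library was left out, which leaves 1 library in its group. A lower count alone therefore does not show that a list leaned on the library left out. The GTPase median was 0.66, 0.66, 0.6 and 0.67 without WT library 1, WT library 2, CKO library 1 and CKO library 2. The 16 higher class I genes became 10, 9 and 9 without WT library 1, CKO library 1 and CKO library 2. The 12 lower glycolysis genes became 7 without CKO library 1, and the 23 lower cell cycle genes became 15, 9, 7 and 13 without WT library 1, WT library 2, CKO library 1 and CKO library 2. The 8 lower matrix genes became 5, 4, 5 and 4 in the same order and the 11 higher ones 7 without CKO library 2. The 2 lower antiviral genes became 1 without WT library 1 or CKO library 1 and were lost without WT library 2 or CKO library 2. The 1 lower class I gene was lost without WT library 1 or either CKO library, and the 2 lower signalling genes became 1 without WT library 2 or either CKO library.

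After IL-4 the genotype comparison asks what differs in the alternatively activated state. Neutrophil genes rose in 14 of 23 cases (20 adjusted over the list alone), with a median log2 fold change of 2.11, as in S100a8 (7.07 ± 0.443 to 42.2 ± 1.21 CPM, edgeR adjusted p = 0.000483) and the granule gene Ngp (log2 fold change 2.14 ± 0.24). Monocyte markers rose in 10 of 15 cases (10 adjusted over the list alone), with Fn1, the fibronectin gene, at 190 ± 41.9 CPM in WT and 592 ± 47.6 in CKO. Spp1, the gene of osteopontin, a matrix protein of tumour and repair macrophages, fell from 2160 ± 368 to 743 ± 77.1 CPM (log2 fold change −1.54 ± 0.17, edgeR adjusted p = 0.000526). Matrix genes as a list rose in 4 of 35 cases and fell in 9 (5 and 12 adjusted over the list alone), and the list was not past the test (camera adjusted p = 0.0987). C1qa, C1qb and C1qc fell by 2.95, 1.89 and 1.58 on the log2 scale while C3 rose by 1.91, so that complement had 1 rise and 4 falls among 18 (1 and 6 adjusted over the list alone). Col18a1, the precursor gene of endostatin, fell by 2.30 and Sel1l3 by 1.85, while Abca9, Id3 and Sik1 rose by 4.55, 2.54 and 2.57. Of the IL-4 list 6 of 38 rose (13 higher and 3 lower adjusted over the list alone), with the crosslinking enzyme gene Tgm2 at a log2 fold change of 1.31 ± 0.13.

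After IL-4 edgeR called 482 genes between genotypes, 229 higher and 253 lower in CKO, and 164, 128 and 162 without WT library 1, WT library 2 and CKO library 1. Camera called neutrophil genes up (adjusted p = 9.48e-43; adjusted p = 0.0171 with an estimated correlation), monocyte markers up (camera adjusted p = 4.59e-21; adjusted p = 0.00695 with an estimated correlation) and the IL-4 list up (camera adjusted p = 1.92e-05; adjusted p = 0.256 with an estimated correlation). The IL-4 list was past camera without cytokine too. Its medians there were 0.36, 0.47, −0.06 and 0.72 without untreated WT library 1 and 2 and CKO library 1 and 2, in that order. Its interaction median lay between −0.2 and 0.16 in the fits that leave out 1 library, so a larger response to IL-4 in CKO was not shown. Macrophage identity was down (camera adjusted p = 1.98e-05; adjusted p = 0.0348 with an estimated correlation) with a mean of −0.47 and a median of 0.02, which was 0, 0.04, −0.05 and 0.08 without WT library 1, WT library 2, CKO library 1 and CKO library 2. Complement was down (camera adjusted p = 0.0389; adjusted p = 0.372 with an estimated correlation; camera adjusted p = 0.144 without CKO library 2) with a mean of 0.15 and a median of −0.14, which was −0.02, −0.03, −0.25 and 0.01 without the same libraries in that order. The 14 higher neutrophil genes became 9, 7 and 9, and the 10 higher monocyte markers 4, 2 and 5, without WT library 1, WT library 2 and CKO library 1. The 6 higher IL-4 genes became 2, 2 and 3 without those libraries, the 9 lower matrix genes 1, 2 and 1, and the 4 higher ones 2, 1 and 1.

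**Figure D3:**
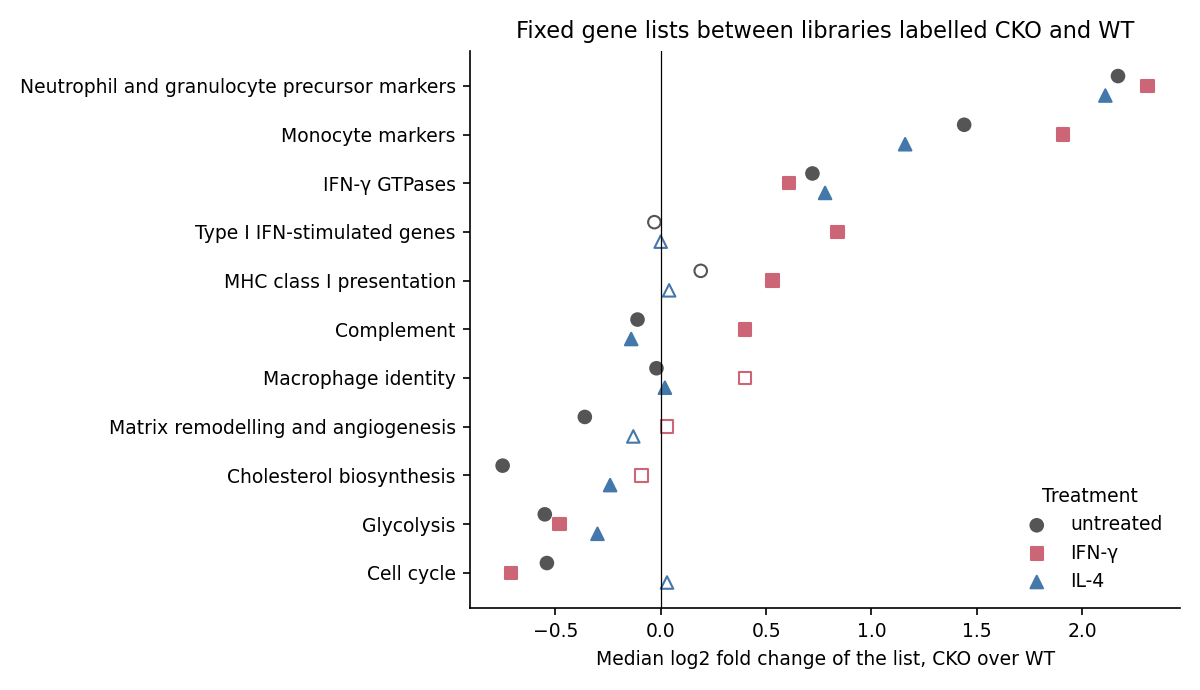
Median log2 fold change, CKO over WT, of the tested members of selected fixed gene lists without cytokine, after IFN-γ and after IL-4. Filled markers are lists with a camera adjusted p under 0.05. Neutrophil markers have medians of 2.17, 2.31 and 2.11 in that order. Responses to the cytokines and interactions are not drawn.

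Across treatments the genotype calls overlapped. Among genes higher in CKO, 661 were shared by the untreated and IFN-γ comparisons, against 145 for independent lists, 201 by untreated and IL-4 (19.7 for independent lists), and 175 by IFN-γ and IL-4 (23.8 for independent lists). Among genes lower in CKO the shared numbers were 552, 206 and 147 (122, 23.7 and 20.3 for independent lists), and 60, 3 and 15 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r of 0.58, 0.63 and 0.50 and Spearman rho of 0.58, 0.60 and 0.43. The libraries of the 3 comparisons differ, but cultures may share animals. In all 3 treatments 166 genes were higher and 133 lower. The higher set held, with log2 fold changes without cytokine, after IFN-γ and after IL-4, the bone morphogen gene Bmp2 (3.38, 4.24 and 2.38), the microglia gene Tmem119 (0.99, 2.47 and 1.15), the neutrophil elastase gene Elane (3.17, 3.70 and 2.52) and the stem cell marker Cd34 (2.22, 1.59 and 1.09). The lower set held Pdpn, a platelet-binding glycoprotein gene (−3.65, −1.80 and −3.32), the growth factor gene Hbegf (−2.21, −3.80 and −1.45), the Notch ligand gene Jag1 (−2.88, −1.33 and −1.59) and the urokinase gene Plau (−2.15, −1.70 and −1.38). These 8 genes were picked after their values were seen.

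IFN-γ against untreated in WT asks what the cytokine changes in the reference genotype. All 20 GTPases rose (20 adjusted over the list alone), with a median log2 fold change of 9.31. Iigp1, which coats pathogen vacuoles, rose from 0.327 ± 0.0676 to 2180 ± 90.8 CPM (log2 fold change 12.68 ± 0.24, edgeR adjusted p = 1.71e-11). Against counts of 0 in both untreated libraries, Serpina3f, a protease inhibitor gene, rose at least 7620-fold and Gbp11 at least 1520-fold, from a floor of 3 counts over the group. Antigen presentation rose on both arms: 23 of 23 class I genes (23 adjusted over the list alone) and 12 of 15 class II genes (12 adjusted over the list alone). Cd74, the class II invariant chain gene, went from 17.7 ± 0.546 to 1080 ± 45.4 CPM and Ciita, its regulator, from 0.69 ± 0.0859 to 182 ± 14.6. Antiviral genes rose in 40 of 43 cases (42 adjusted over the list alone) and IFN-γ signalling genes in 24 of 29 with 1 fall (24 and 1 adjusted over the list alone). Acod1, which makes the antimicrobial metabolite itaconate, rose by a log2 fold change of 5.76 ± 0.16. Cd274, the gene of the checkpoint ligand PD-L1, rose from 30.4 ± 3.4 to 802 ± 91.8 CPM, and costimulation genes rose in 8 of 16 cases and fell in 1 (9 and 3 adjusted over the list alone).

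Cholesterol synthesis fell after IFN-γ in WT in 21 of 24 cases (1 higher and 22 lower adjusted over the list alone), with a median of −1.53, as in Hmgcs1 (248 ± 30.8 to 73.5 ± 3.02 CPM). Glycolysis rose in 14 of 20 cases and fell in 1 (16 and 1 adjusted over the list alone), with Pfkp at a log2 fold change of 1.81 ± 0.11. Known IRF8-dependent genes rose in 24 of 36 cases and fell in 3 (24 and 3 adjusted over the list alone), for example Il18bp, an interleukin trap gene (6.13 ± 0.227 to 158 ± 11.7 CPM). Single genes that dropped were the mannose receptor gene Mrc1, from 2090 ± 47.5 to 416 ± 22.4 CPM, the clotting factor gene F13a1, from 244 ± 11.2 to 26.9 ± 0.973 CPM, and Mmp12 by a log2 change of −2.67. In all, edgeR called 3935 genes, 2018 higher and 1917 lower, and 2611 without untreated WT library 1. Camera called the GTPases up at an adjusted p of 1.25e-192 and antiviral genes at 1.73e-92 (adjusted p = 0.000991 and 0.00422 with an estimated correlation). Class I, class II and signalling genes were up (camera adjusted p = 1.81e-56, 8.97e-43 and 8.9e-67; adjusted p = 0.006, 0.00732 and 0.00195 with an estimated correlation), and IRF8-dependent genes were up (camera adjusted p = 7.07e-18; adjusted p = 0.0356 with an estimated correlation). Glycolysis (camera adjusted p = 8.7e-06; adjusted p = 0.223 with an estimated correlation) was up and cholesterol synthesis down (camera adjusted p = 5.78e-19; adjusted p = 0.0756 with an estimated correlation).

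IFN-γ against untreated in CKO asks the same of the other genotype. All 43 antiviral genes rose (43 adjusted over the list alone), with a median log2 fold change of 3.49 and Ifit2 going from 8.53 ± 0.603 to 1050 ± 39.5 CPM (log2 fold change 6.94 ± 0.18, edgeR adjusted p = 1.57e-10). All 20 GTPases and all 23 class I genes rose (20 and 23 adjusted over the list alone), as did 12 of 15 class II genes with 1 fall (12 and 1 adjusted over the list alone). Cxcl9, a chemokine gene that draws T cells, rose at least 3750-fold and Serpina3f at least 6970-fold over a floor of 3 counts in the untreated group. Complement rose in 13 of 18 cases (13 adjusted over the list alone), with C3 going from 38.7 ± 3.87 to 729 ± 54 CPM and C1ra at a log2 fold change of 3.96 ± 0.18. Inflammatory cytokines rose in 15 of 24 cases and fell in 2 (15 and 2 adjusted over the list alone), including the T cell chemokine gene Ccl5 (0.453 ± 0.111 to 21.7 ± 4.2 CPM). Cholesterol synthesis fell in 15 of 24 cases and rose in 1 (15 and 1 adjusted over the list alone), with a median of −0.73, and glycolysis rose in 14 of 20 and fell in 1 (17 and 1 adjusted over the list alone). Decreases included Itgb3, an adhesion receptor gene (13.2 ± 0.12 to 1.4 ± 0.0913 CPM), the homing receptor gene Cxcr4 (49 ± 9.1 to 6.21 ± 0.212 CPM) and F13a1 (log2 fold change −2.91 ± 0.11). In this comparison edgeR called 4333 genes, 2396 higher and 1937 lower, with 2722 without IFN-γ CKO library 1 and 2675 without IFN-γ CKO library 2. The 15 higher cytokines became 8 without untreated CKO library 1 and 8 without IFN-γ CKO library 2, and the 14 higher glycolysis genes 9 without IFN-γ CKO library 2. The 2 lower cytokines became 1 without untreated CKO library 1 or IFN-γ CKO library 2. The 1 lower class II gene and the 1 higher cholesterol gene were lost without untreated CKO library 1 or either IFN-γ CKO library. Camera called antiviral genes and complement up (adjusted p = 2.51e-130 and 2.31e-18; adjusted p = 0.00151 and 0.00456 with an estimated correlation), cytokines up (camera adjusted p = 0.000126; adjusted p = 0.0931 with an estimated correlation) and cholesterol synthesis down (camera adjusted p = 1.4e-05; adjusted p = 0.339 with an estimated correlation). Of the genes called in both genotypes, 1530 rose in both and 1126 fell in both (297 and 228 for independent lists), and 40 went opposite ways. The fold changes correlated across genes, which are not independent replicates, with Pearson r of 0.83 and Spearman rho of 0.66.

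**Figure D4:**
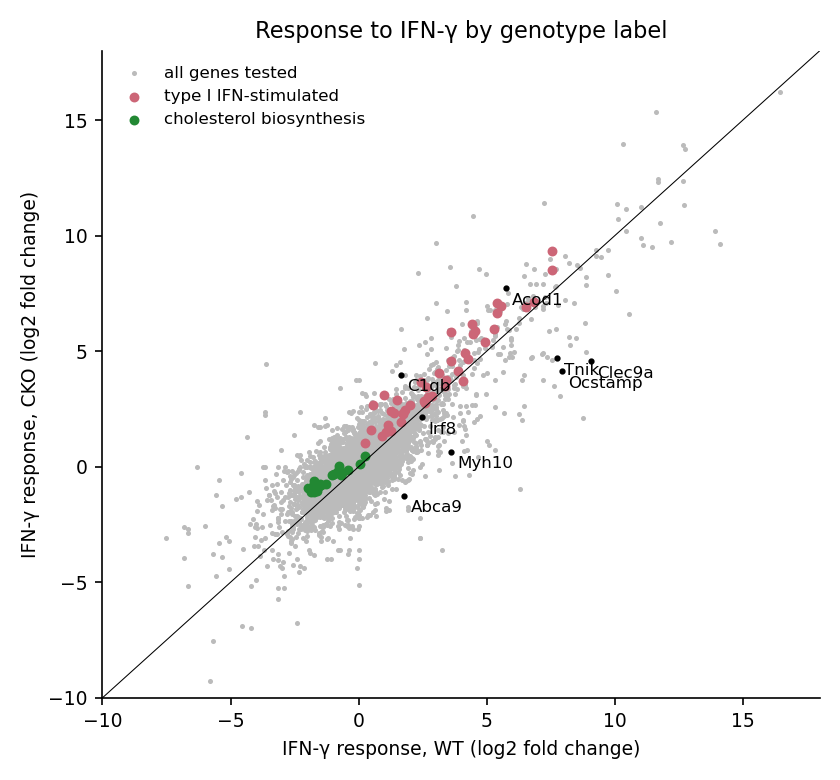
Log2 fold change after IFN-γ in libraries labelled CKO (vertical axis) against WT (horizontal axis), 1 point per tested gene, with the line of equal change. Colours mark members of the antiviral and cholesterol synthesis lists, and not genes past the interaction test. Of the genes named in the figure, C1qb lies above the line, with an interaction of 2.34. Clec9a and Ocstamp lie below it, with −4.48 and −3.80.

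The interaction asks whether the IFN-γ response differs between genotypes. Antiviral genes responded more in CKO in 16 of 43 cases (23 adjusted over the list alone), with a median difference of 0.68: Oasl2 went from 7.4 ± 1.05 to 90.3 ± 5.84 CPM in WT and from 5.06 ± 0.0948 to 286 ± 3.65 in CKO (interaction 2.21 ± 0.19, edgeR adjusted p = 0.000246). Complement genes had positive interactions in 6 of 18 cases (7 adjusted over the list alone). C1qb rose from 487 ± 21.5 to 1530 ± 163 CPM in WT and from 38.9 ± 15 to 614 ± 85.8 in CKO (interaction 2.34 ± 0.32, edgeR adjusted p = 0.00356), and C3 and C1ra had interactions of 1.48 and 1.70. Opposite responses appeared too. Tlr2, a sensor of bacterial lipoproteins, went from 45.8 ± 2.68 to 23.3 ± 0.63 CPM in WT and from 35.4 ± 4.84 to 55 ± 5.44 in CKO (interaction 1.61 ± 0.17), and the fungal sensor gene Clec4e and the inhibitory receptor gene Pilra had interactions of 2.65 and 2.60. Cd14, a receptor for bacterial lipopolysaccharide, fell less in CKO (interaction 1.75 ± 0.17), and so did the growth factor gene Igf1 (1.46 ± 0.16). Responses weaker in CKO were those of Clec9a (interaction −4.48 ± 0.72, edgeR adjusted p = 0.00743), Ocstamp (−3.80 ± 0.39), the myosin gene Myh10 (−2.96 ± 0.21) and the protease gene Ctsc (294 ± 23.4 to 2720 ± 272 CPM in WT, 325 ± 25.9 to 922 ± 171 in CKO). Macrophage identity genes, which went both ways after IFN-γ, had positive interactions in 5 of 26 cases (7 adjusted over the list alone), with Fcgr1 at an interaction of 1.18 ± 0.18. Cholesterol genes, whose untreated level was lower in CKO, had a median interaction of 0.70, with 19 of 24 past the test adjusted over the list alone and 5 of 24 adjusted over all genes. The GTPases split, with Igtp at 1.28 and Gbp8 at −2.61, and as a list they were not past the test (camera adjusted p = 0.152).

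In the IFN-γ interaction edgeR called 443 genes, 337 positive and 106 negative. The count was 189 without untreated WT library 1, 230 without untreated WT library 2, 269 without IFN-γ WT library 1, 226 without IFN-γ WT library 2, 940 without untreated CKO library 2, 168 without IFN-γ CKO library 1 and 137 without IFN-γ CKO library 2. Camera called antiviral genes up (adjusted p = 7.03e-25; adjusted p = 0.08 with an estimated correlation), complement up (camera adjusted p = 4.14e-08; adjusted p = 0.0509 with an estimated correlation), cholesterol synthesis up (camera adjusted p = 6.9e-15; adjusted p = 0.191 with an estimated correlation) and macrophage identity up (camera adjusted p = 2.83e-05; adjusted p = 0.0488 with an estimated correlation). The 16 antiviral genes became 7 without untreated WT library 1, 9 and 8 without IFN-γ WT library 1 and 2, and 6 and 7 without IFN-γ CKO library 1 and 2. The 6 complement genes became 3 without either of those CKO libraries. The 5 identity genes became 3 without untreated WT library 2, IFN-γ WT library 1 or IFN-γ CKO library 1 or 2. The 5 cholesterol genes became 3 without untreated WT library 1 or IFN-γ WT library 2, 1 without untreated CKO library 1 and 17 without untreated CKO library 2. In edgeR fits without untreated WT library 2, IFN-γ WT library 1 or IFN-γ CKO library 1 or 2 the number was 0, while 18, 19, 18 and 18 of the 24 had an unadjusted p under 0.05. DESeq2 was not run on these fits.

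IL-4 against untreated in WT asks what alternative activation changes. The fixed IL-4 list rose in 31 of 38 cases and fell in 1 (34 and 1 adjusted over the list alone), with a median log2 fold change of 3.34. Arg1, the arginase gene that marks repair macrophages, rose from 1.05 ± 0.446 to 2660 ± 371 CPM (log2 fold change 11.30 ± 0.70, edgeR adjusted p = 1.73e-05). Mgl2, a lectin gene, rose from 1.09 ± 0.00586 to 604 ± 25.6 CPM, and Chil3, a chitinase-like gene, from 11.7 ± 0.98 to 601 ± 216. Retnla, a secreted protein gene of allergic inflammation, rose 7360-fold (95% counting interval 2040 to 60800), and the ribonuclease gene Rnase2a at least 1420-fold. Vessel and matrix genes rose in 14 of 35 cases and fell in 5 (14 and 6 adjusted over the list alone), among them Flt1, a VEGF receptor gene (0.467 ± 0.13 to 52.3 ± 4.66 CPM), Fn1 (log2 fold change 3.86 ± 0.16) and Mmp13 (2.18 ± 0.16). The transferrin receptor gene Tfrc, which takes up iron, rose from 723 ± 18.2 to 2830 ± 105 CPM. Class II genes rose in 7 of 15 cases (7 adjusted over the list alone), with Cd74 at a log2 fold change of 2.58 ± 0.13. Sensors of microbes fell in 9 of 33 cases and rose in 4 (11 and 5 adjusted over the list alone), as in Tlr2 (45.8 ± 2.68 to 8.78 ± 0.536 CPM), Nlrp3 (log2 fold change −1.55 ± 0.12) and, from the identity list, Cd14 (−2.43 ± 0.13). Antiviral genes fell in 11 of 43 cases and rose in 3 (12 and 3 adjusted over the list alone), with Usp18 at 1.78 and Oas2 at −1.46.

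For IL-4 in WT edgeR called 1992 genes, 1081 higher and 911 lower. The count was 962 without untreated WT library 1, 1072 without untreated WT library 2, 898 without IL-4 WT library 1 and 920 without IL-4 WT library 2. Camera called the IL-4 list up (adjusted p = 6.26e-140; adjusted p = 0.000154 with an estimated correlation), matrix genes up (camera adjusted p = 0.000176; adjusted p = 0.0495 with an estimated correlation), class II up (camera adjusted p = 3.55e-08; adjusted p = 0.275 with an estimated correlation) and microbial sensors down (camera adjusted p = 0.00035; adjusted p = 0.575 with an estimated correlation). Antiviral genes were down (camera adjusted p = 0.0187; adjusted p = 0.791 with an estimated correlation; camera adjusted p = 0.0748 without untreated WT library 1). Their 11 falls became 2, 4 and 3, and the 9 falls among sensors 5 each, without untreated WT library 1, IL-4 WT library 1 and IL-4 WT library 2. The 5 falls among matrix genes became 3 without untreated WT library 2 or either IL-4 WT library. The 3 rises among antiviral genes became 1, and the 1 fall in the IL-4 list was lost, without any one of the 4 libraries. The 4 rises among sensors became 2 without untreated WT library 1 or IL-4 WT library 2, 1 without untreated WT library 2, and were lost without IL-4 WT library 1.

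In CKO the IL-4 list rose in 33 of 38 cases (33 adjusted over the list alone), with a median of 3.05. Arg1 rose from 1.73 ± 1.75 to 1520 ± 449 CPM (log2 fold change 9.87 ± 0.66, edgeR adjusted p = 2.1e-05), Fn1 from 25.7 ± 1.73 to 592 ± 47.6, and Slc7a2, which imports arginine, by a log2 fold change of 5.96 ± 0.16. Matrix genes rose in 16 of 35 cases and fell in 6 (16 and 8 adjusted over the list alone), with the galectin gene Lgals3 going from 1520 ± 44.8 to 4520 ± 198 CPM. Cholesterol synthesis rose in 20 of 24 cases (22 adjusted over the list alone), with a median of 0.62, for example Mvd (27.2 ± 2.74 to 62.2 ± 2.21 CPM). Antiviral genes fell in 17 of 43 cases and rose in 4 (18 and 5 adjusted over the list alone), as in Ifit1 (log2 fold change −2.33 ± 0.29). Cx3cr1 fell from 15.4 ± 3 to 0.462 ± 0.0324 CPM and the laminin gene Lama3 from 50.5 ± 2.58 to 8.25 ± 0.687. Here edgeR called 3664 genes, 1828 higher and 1836 lower, with 2031 without untreated CKO library 1 and 1725 without IL-4 CKO library 2. Camera called the IL-4 list up (adjusted p = 7.99e-109; adjusted p = 0.000176 with an estimated correlation), matrix up (camera adjusted p = 1.15e-06; adjusted p = 0.0146 with an estimated correlation), cholesterol up (camera adjusted p = 5.54e-08; adjusted p = 0.472 with an estimated correlation) and antiviral genes down (camera adjusted p = 0.000623; adjusted p = 0.606 with an estimated correlation). The 20 cholesterol genes became 9 without untreated CKO library 1 or IL-4 CKO library 2, and the 17 antiviral falls became 9 and 8. The 4 antiviral rises became 1 without IL-4 CKO library 1. Across genotypes 864 genes rose in both and 699 fell in both (121 and 103 for independent lists), 3 went opposite ways, and the fold changes correlated across genes, which are not independent, with Pearson r of 0.78 and Spearman rho of 0.64.

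The IL-4 interaction asks whether that response differs between genotypes. Acod1 fell from 8.03 ± 0.308 to 1.94 ± 0.259 CPM with IL-4 in WT and was at 3.94 ± 0.436 and 6.13 ± 1.36 CPM in CKO (interaction 2.71 ± 0.23, edgeR adjusted p = 0.00136). Chil3 stood at 601 ± 216 CPM in WT and 632 ± 86 in CKO after IL-4, from untreated levels of 11.7 ± 0.98 and 93.2 ± 20.4, so that its rise was smaller in CKO (interaction −2.92 ± 0.33, edgeR adjusted p = 0.0165). Prps1, which makes a precursor of nucleotides, rose from 14.5 ± 0.0702 to 30.2 ± 0.564 CPM in WT and from 9.09 ± 2.12 to 67.7 ± 7.85 in CKO (interaction 1.83 ± 0.23, edgeR adjusted p = 0.0183). Flrt2 and Angptl2 had interactions of 1.23 and 1.12 and Ermard of −1.39, which completes the 6 genes edgeR called. The count was 1 without untreated WT library 1, 2 without untreated WT library 2, 2 and 3 without IL-4 WT library 1 and 2, and 329 without untreated CKO library 2. Of the 6, Acod1 was kept in all 8 fits that leave out 1 library. Flrt2 was lost without untreated WT library 1, IL-4 WT library 1 or IL-4 WT library 2 (highest edgeR adjusted p = 0.119), Chil3 and Prps1 in 5 of the 8 fits (highest edgeR adjusted p = 0.197 and 0.192) and Angptl2 and Ermard in 7 of the 8 (highest edgeR adjusted p = 0.302 and 0.304). Cholesterol synthesis genes as a list had a median interaction of 0.54 (camera adjusted p = 4.88e-18; adjusted p = 0.321 with an estimated correlation). Adjusted over all genes 0 of its 24 members passed with edgeR and 0 with DESeq2, where 16 and 17 had an unadjusted p under 0.05. Adjusted over the list alone 10 passed with edgeR. The list median was 0.38 without untreated CKO library 1 and 0.67 without untreated CKO library 2. The fit without untreated CKO library 2 keeps only library 1 of that group, which stood apart. Cell cycle genes had a median of 0.53 (camera adjusted p = 4.88e-18; adjusted p = 0.685 with an estimated correlation), which was 0.24 without untreated CKO library 1, 0.91 without untreated CKO library 2 and 0.30 without IL-4 CKO library 2. Monocyte markers had a median of −0.36 (camera adjusted p = 0.00374; adjusted p = 0.321 with an estimated correlation), which was −0.23 without untreated WT library 2 and 0.05 without untreated CKO library 1.

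The IFN-γ and IL-4 responses in WT overlapped. Of the genes called in both, 297 rose in both and 389 fell in both (134 and 107 for independent lists), and 357 went in opposite directions. No value for independent lists was computed for the opposite calls. The excess of shared rises and falls alone therefore does not show that the 2 cytokines moved genes in the same direction. Mrc1 and Itgb3 were of the opposite kind, with log2 fold changes of −2.33 and −5.07 after IFN-γ and 1.10 and 2.96 after IL-4. Cd14 fell in both, by 2.52 and 2.43 on the log2 scale, and C3 rose in both, by 2.76 and 1.33. Both responses use the same 2 untreated libraries. Across genes, which are not independent, the fold changes correlated with Pearson r of 0.17 and Spearman rho of 0.22, and the covariance was 0.148. In 20 simulations of unchanged WT groups, with the controls drawn anew and only WT libraries fitted, the mean r was 0.48 and the mean covariance 0.0368. The largest number of shared calls was 1. With no gene changed few calls can arise, so that number does not tell how shared controls act where many genes change. Part of the excess may come from the shared controls, which are too few to split.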

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

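All the tests of explanations in this part were chosen only after the result was seen, and the interactions were planned. The interactions test whether a response to a cytokine differs between the libraries labelled CKO and WT. For IFN-γ edgeR called 443 genes, with 940 without untreated CKO library 2, 189 and 230 without untreated WT library 1 and 2, 269 and 226 without IFN-γ WT library 1 and 2, and 168 and 137 without IFN-γ CKO library 1 and 2. The most positive terms by the naming rule, where the change was higher in CKO, were Clec4e (2.65), Pilra (2.60), Ednrb (2.36), C1qb (2.34) and Marcksl1 (2.34). The most negative were Clec9a (−4.48), Ocstamp (−3.80), Tnik (−3.06), Abca9 (−3.04) and Myh10 (−2.96). Of these 10, 8 kept their call in each of the 8 fits that leave out 1 library. Marcksl1 lost it without IFN-γ WT library 1 (edgeR adjusted p = 0.0527), and Tnik lost it without untreated WT library 2, untreated CKO library 1 or untreated CKO library 2 (edgeR adjusted p = 0.0537, 0.0806 and 0.0775). For IL-4 edgeR called 6 genes: Acod1 (2.71), Prps1 (1.83), Flrt2 (1.23), Angptl2 (1.12), Ermard (−1.39) and Chil3 (−2.92). The number of calls was 1, 2, 2 and 3 without untreated WT library 1, untreated WT library 2, IL-4 WT library 1 and IL-4 WT library 2, and 329 without untreated CKO library 2. Acod1 kept its call in each of the 8 fits (highest edgeR adjusted p = 0.0168). Flrt2 lost it in 3 (without untreated WT library 1 and IL-4 WT library 1 or 2), Prps1 and Chil3 in 5 each, and Angptl2 and Ermard in 7 each, all but the fit without untreated CKO library 2.

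The libraries labelled CKO had more Irf8 counts and far fewer Lyz2 counts than those labelled WT. The tables argue against 1 library with a wrong genotype label, since the lowest Lyz2 CPM of a WT library was 209 times the highest of a CKO library. Treatment and replicate labels are not checked by Lyz2. An altered Lyz2 allele in the cells labelled CKO, such as a recombinase gene inserted there, has the values it needs: the larger of the Lyz2 interactions was −0.11 on the log2 scale, so the difference was alike in every treatment. Labels exchanged between the whole groups are argued against as well, because the libraries labelled CKO would then be wild-type macrophages, in which Lyz2 is an abundant transcript, and the highest of the 6 held 28 CPM. The higher Irf8 counts (log2 fold change 1.57 without cytokine) stay unexplained, since counts cover the whole gene and a transcript that lacks part of its sequence was not tested.

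Neutrophil and monocyte markers were higher in the libraries labelled CKO in all 3 treatments. A lower share of macrophages could raise the markers of all other cell types alike. The median of 23 neutrophil markers was 1.99 (SD 0.87, mean of the 3 treatments) and that of 32 pooled markers of other types 0.13 (SD 0.81). The difference was 1.86 (two-sided permutation test over genes, p = 2e-05, where the smallest these 1e+05 resamples can give is 1e-05). Neutrophil markers thus differed more than the pool. The test does not decide on the share of macrophages, because it treats genes as independent, although markers of 1 cell type can move together. The pool also holds genes such as Tfrc and Igfbp4, which had many counts in the WT cultures and need not rise when that share falls. The RNA of untreated CKO library 1 is argued against, since the smaller median in the comparisons without it, after IFN-γ and after IL-4, was 2.11. More granulocyte and monocyte precursors in the culture and more of these transcripts per macrophage cannot be told apart, because bulk counts do not separate cells: 21 of the 23 neutrophil markers were positive in all 3 treatments, as either would give. Among the 15 monocyte markers 15 were positive in all 3, with a median of 1.56.

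Of genes that differed between the labels in 1 direction in all 3 treatments, Rps2, its pseudogenes Rps2-ps10, Rps2-ps11 and Rps2-ps13, Nnt, Wdfy1 and Glo1 were examined. A sequence difference that moves Rps2 reads between the gene and its copies has the values it needs: Rps2-ps13 had a log2 fold change of −2.38 without cytokine and Rps2 of 0.57, while the summed family of 7 genes differed by at most 0.14 on the log2 scale (405 ± 5.84 against 409 ± 27 CPM without cytokine). Chromosome segments around Irf8 and Lyz2, carried along if these genes were changed in the cells labelled CKO, are argued against for the 4 named genes Rps2, Nnt, Wdfy1 and Glo1, of which 0 lie on chromosome 8 or 10. Within 10 Mb of Irf8 or Lyz2, 6 of 252 genes were called in 1 direction in all 3 treatments (2 of 178 near Irf8 and 4 of 74 near Lyz2). Of all 16218 genes with a position 298 were so called (odds ratio of near against the others 1.31, Fisher's exact test two-sided p = 0.47). The shares were 1.12% near Irf8, 5.41% near Lyz2 and 1.84% of all. These counts include Irf8 and Lyz2 themselves, and the window holds Lyz1, so the test does not decide whether neighbouring genes were carried along. A different genetic background of the mice labelled CKO and WT was not tested, since background and label are confounded in this design.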

How the results depend on the processing

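The alternative that leaves untreated CKO library 1 out of the shared spread was chosen only after the result was seen; the other alternatives were planned. No named gene past the test in either fit changed direction under an alternative. Of the named values, 653 of 660 kept their side of the threshold with DESeq2, 659 with DESeq2 size factors, 644 without a filter on low counts and 578 of 583 with a stricter filter. With only the compared groups in the fit 55 of 656 lost their call, and 352 of 2976 values did so with 1 library left out. Requiring a 2-fold change left 861, 1032 and 264 genotype calls without cytokine, after IFN-γ and after IL-4, 1752 and 1835 IFN-γ calls and 809 and 1204 IL-4 calls in WT and CKO, and 265 IFN-γ interactions, because the criterion is narrower. DESeq2 gave 42 IL-4 interactions. Without a filter the genotype calls after IL-4 were 1129 and the interactions 1019 and 291, and with the stricter filter genotype calls after IL-4 were 290. Fits of only the compared groups gave 836 and 310 genotype calls without cytokine and after IL-4, 3562 and 1216 IL-4 calls in WT and CKO, 289 IFN-γ interactions and 0 IL-4 interactions with edgeR (748 genes at an unadjusted p under 0.05, and 42 calls with DESeq2 on all libraries; DESeq2 was not run on these groups alone). Libraries share only a number, and the meaning of the 2 numbers is not stated. Same-numbered libraries had deviations that correlated from 0.11 to 0.73 in WT and from 0.32 to 0.54 in CKO. Between the genotypes they correlated from −0.05 to 0.42. With the replicate block the genotype calls after IL-4 were 860 and the interactions 732 and 26, and with the replicate block within genotype IL-4 calls in WT were 3023 and the interactions 1080 and 85. The replicate block ended the camera calls without cytokine of the IL-4 list (adjusted p = 0.0518) and macrophage identity (adjusted p = 0.0563) and added inflammatory cytokines without cytokine (camera adjusted p = 0.00625) and immediate-early genes after IL-4 (camera adjusted p = 0.0295). It changed no other list call. Leaving out 1 library gave 866 to 5034, 1209 to 1890 and 128 to 651 genotype calls, 2611 to 3121 and 2675 to 5256 IFN-γ calls in WT and CKO, 898 to 1072 and 1725 to 5217 IL-4 calls, and 137 to 940 and 1 to 329 interactions. Irf8 after IL-4 in WT ranged from −0.48 to −0.37 and was then not past the test. The 1 reversal was the cell cycle list in the IFN-γ interaction, down in all libraries (camera adjusted p = 0.0399), with adjusted p from 2.57e-15 to 0.409 and up without untreated CKO library 2 (camera adjusted p = 0.0415). Camera calls were lost for 70 of 207 list results with an estimated correlation and for 34 with fry, which added 15 calls. Without untreated CKO library 1 in the shared spread, genotype calls were 3925 after IFN-γ and 665 after IL-4, and WT calls 4578 and 2494. Where no reason is given, the cause was not tested. Depth limits genes of few counts: a floor of 3 counts bounds their folds.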

Other observations

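The comparisons and lists in this part were planned, and the values of Xist and the Y-linked genes were chosen only after the result was seen. Other lists moved with the cytokines. Erythroid and megakaryocyte genes fell after IFN-γ in 4 of 6 cases in WT (4 adjusted over the list alone; camera adjusted p = 3.6e-06) and in 4 of 6 in CKO (4 adjusted over the list alone; camera adjusted p = 2.61e-05). Tfrc, which takes up iron, dropped from 723 ± 18.2 to 176 ± 19 CPM in WT and from 675 ± 9.94 to 275 ± 38.4 in CKO, and Ppbp, a platelet chemokine gene, fell at least 50.2-fold in CKO. After IL-4 Itgb3 and Tfrc rose in both genotypes, Itgb3 from 18.4 ± 4.61 to 143 ± 5.23 CPM in WT. Dendritic cell markers rose after IFN-γ in WT in 6 of 13 cases (6 adjusted over the list alone; camera adjusted p = 0.00074), with Clec9a going from 0.0865 ± 0.0259 to 48.2 ± 6.35 CPM. In CKO 5 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.174; 1 fell without untreated CKO library 2), and the list interaction was down (camera adjusted p = 0.0388; adjusted p = 0.191 with an estimated correlation), a call lost without untreated WT library 2, IFN-γ WT library 1 or 2, untreated CKO library 1 or IFN-γ CKO library 2. Among stromal markers, 1 of 6 rose and 1 fell after IFN-γ in WT (1 and 1 adjusted over the list alone; camera adjusted p = 0.796): the fibrillin gene Fbn1 rose 135-fold (95% counting interval 37 to 1120) and Igfbp4, which binds insulin-like growth factors, went from 255 ± 10.5 to 101 ± 4.38 CPM.

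Stress and immediate-early genes rose after IFN-γ in CKO in 12 of 23 cases (13 and 1 lower adjusted over the list alone; camera adjusted p = 0.005; adjusted p = 0.226 with an estimated correlation), with the amino acid stress genes Asns and Trib3 at log2 fold changes of 1.86 and 3.06. Lipid and lysosome genes were higher in CKO after IFN-γ in 9 of 32 cases and lower in 3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.00372; adjusted p = 0.631 with an estimated correlation), including the lipid droplet gene Plin2 (547 ± 23 to 1190 ± 82.5 CPM). The 9 became 3 without IFN-γ WT library 1 or IFN-γ CKO library 1, and 4 without IFN-γ CKO library 2, and the 3 became 1 without any one of the 4 libraries. Of 4 lymphoid markers, too few to test as a list, 2 were higher and 1 lower in untreated CKO (2 and 1 adjusted over the list alone), with 1 higher without either WT library or CKO library 1. Cd4 went from 2.78 ± 0.221 to 16.6 ± 3.09 CPM and the interleukin-7 receptor gene Il7r from 110 ± 16.2 to 26.5 ± 3.36. Of 3 mast cell and basophil markers 1, the histamine enzyme gene Hdc, rose after IFN-γ, from 0.154 ± 0.119 to 1.78 ± 0.476 CPM in WT and from 0.391 ± 0.145 to 5.63 ± 0.921 in CKO (1 adjusted over the list alone in each). The 3 sex-specific genes tested had a median log2 fold change of 0.24 between untreated genotypes, which was 0.15 without WT library 2, 0.11 without CKO library 1 and 0.41 without CKO library 2. Xist lay between 1150 and 1640 CPM in all 12 libraries, and of the genes on the Y chromosome Ddx3y had 0 counts in each, Eif2s3y at most 1 and Kdm5d 30 to 59.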
